A study of Homo sapiens with 9 samples.

How the data were processed

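Total RNA from 9 human oesophageal adenocarcinoma cell lines was sequenced, per the labels, after growth to 80% confluency without treatment. Per the labels, RNA was purified on spin columns after homogenisation and libraries followed standard Illumina protocols, and the design text mentions 3 technical replicates of each line. How those replicates enter the single column of each line is not given in the sources used here. Per the submitters' processing notes, the authors used STAR 2.6.1d, FastQC 0.11.7 and R 3.6.1 with the genome build GRCh37. The program that counted reads, the annotation release and the strand setting are not given there, so reads of a gene and of an overlapping or antisense gene cannot be told apart.

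The deposited count table holds raw, unnormalised whole-number counts for 52158 named genes in 9 columns, per the file headers and the values, plus 1 blank name that held 0.00485% to 0.00965% of counts and was left out. Deposited files of each line hold union-mode counts and the authors' FPKM for 57905 gene identifiers, together with a deposited gene length, per the file headers. From the values, each deposited FPKM is the count divided by that gene length and by the sum of all counts in the same file. Of 50418 identifiers with a name in the table, 49075 (97.3%) had equal counts in both, and 1343 did not. Over the 49075 identifiers each of the 9 columns matched the file of its own line, where the column named OACM5.1_C was taken as the line labelled OAC_5.1_C. Counts outside the table made up 25.8% (OE19) to 77.3% (JH_EsoAd1) of the counts in the files of the lines. GENCODE release 29 gave a name, biotype and chromosomal order to 49791 of the 52158 genes and was used for nothing else, since it is on another build, so no coordinates are given. List symbols matched the table for 457 of 459, and PECAM1 was among those without a match. The listed names CTGF, CYR61 and PVRL4 appear under their current names CCN2, CCN1 and NECTIN4.

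Counts were scaled to CPM with TMM factors (edgeR 4.0.16 in R 4.3.3), which ranged from 0.831 (JH_EsoAd1) to 1.11 (ESO-51), and used as log2(CPM + 1). Library size alone would shift the median gene by -0.25 in JH_EsoAd1 and 0.14 in ESO-51 on the log2 scale, and DESeq2 1.42.0 size factors by -0.02 to 0.02, relative to TMM. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Poisson 95% intervals are exact, shares of counts have Wilson intervals, and a count of 0 is given with a floor of 3 counts, from 0.0400 CPM (FLO-1) to 0.173 CPM (ESO-26). With 1 library per line no test between lines was possible.

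The design, gene lists, relations, rules for naming genes and the first set of alternatives were chosen before the data were examined. A gene was called higher in a library where its log2 value lay at least 2 above the highest of the other 8 and its CPM was at least 5, and lower where it lay at least 2 below the lowest of the other 8 and that lowest CPM was at least 5. Similarity used genes at a CPM of at least 1 in at least 2 libraries, with Pearson and Spearman correlation, average-linkage clustering on 1 - r and principal components of centred values. The genes named were, per library, the 5 protein-coding genes with the largest gap upward and the 2 with the largest gap downward, leaving out mitochondrial and sex-linked marker genes, then the members of lists read gene by gene, up to 4 members of each called list with the largest difference in its direction, and the genes of the relations. A few further list members and neighbours are named as well, chosen after their values were seen, and some genes and 1 scored list that these rules select are not reported here.

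Scored lists, 29 in number, included columnar transcription factors, intestinal, gastric and squamous differentiation, epithelial junctions and splicing, mesenchymal genes, matrix proteases, mitosis, DNA replication, interferon response, MHC class I and class II presentation, NF-kB cytokines, hypoxia and glycolysis, NRF2 targets, cholesterol synthesis, the unfolded protein response, drug transport and metabolism, Wnt targets, YAP targets, bile acid handling, cancer-testis antigens, mucins, neuroendocrine genes, posterior HOX genes, haematopoietic cells, endothelial cells and the neighbours of ERBB2 on 17q12. ERBB2 itself was a member of the 17q12 list. Receptor tyrosine kinases, amplified genes, tumour suppressors, mismatch repair genes, cytotoxic drug targets and surface antigens were read gene by gene. A list's value is the median over members, at a CPM of at least 1 in at least 1 library, of the log2 value minus the median of the other 8 libraries. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called at or beyond percentile 1 or 99. For 14 relations across the 9 libraries, Pearson r and Spearman rho were given with exact two-sided permutation p over 362880 pairings (smallest possible p 5.5e-06), Benjamini-Hochberg adjusted over the 14, and r again without the 2 libraries farthest from the median of the first measure. Where libraries fell into 2 clusters no pooled r was given. No sequencing batch or date is given in the labels, so no within-batch value could be computed.

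The rules were tested on simulated data with 52158 genes at the real means and library sizes. Of 100 genes raised 16-fold in 1 library 100 were recovered, and of 100 lowered 16-fold 92 were, with 0 calls on unchanged genes in that library. The changed genes had a mean CPM of at least 20, and all libraries shared 1 profile with a dispersion of 0.1. Weaker genes, smaller changes and lines that differ widely were therefore not tried. Random lists gave 23 calls in 900 (2.56%), 20 of 20 lists raised 4-fold were called, and 7 of 200 unrelated pairs had an exact permutation p under 0.05. Alternatives were DESeq2 size factors, library size only, a pseudocount of 5, no CPM minimum or filter, the deposited FPKM, a 2-fold gap, the mean over members, and leaving out each library for the relations; leaving out each library for gene counts and lists and FPKM rescaled to equal sums were added after the data were seen. For the closing section, 7 library measures and 29 list values were compared across the 9 libraries by Dixon's ratio, and neighbouring called genes were counted in gene order against 10000 random draws. This order held only protein-coding genes at a CPM of at least 5, in every other library for low genes and in the library itself for high genes. Neighbours are next to each other in that order, so other genes may lie between them. Counts of identifiers outside the table were not analysed here beyond their share.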

Results

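RNA was sequenced from 9 human cell lines that the labels describe as oesophageal adenocarcinoma, with gastric cardia adenocarcinoma as the source, each grown untreated. OACP4_C, OE19, FLO-1, SK-GT-4, ESO-26, OE33, ESO-51, OAC_5.1_C and JH_EsoAd1 each contributed 1 column of gene counts, so no difference between lines has a replicate check. The table held 57995387 counts for OACP4_C, 29959895 for OE19, 69881539 for FLO-1, 31186139 for SK-GT-4, 16801179 for ESO-26, 24165042 for OE33, 40683038 for ESO-51, 50643672 for OAC_5.1_C and 24290184 for JH_EsoAd1. Between 13687 genes (OE19) and 15236 genes (FLO-1) reached a normalised count rate (CPM) of 1. Mitochondrial genes, almost entirely the ribosomal RNAs MT-RNR1 and MT-RNR2, took 1.48% of counts in ESO-26 and 24.7% in JH_EsoAd1, with 7.04% in OE33 as the next highest share. Wilson 95% intervals of such shares were at most 0.0369 percentage points wide. Levels are CPM after TMM scaling. Their Poisson 95% intervals, and the floor of 3 counts given where a gene had a count of 0, cover counting error only.

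ERBB2, the receptor tyrosine kinase HER2, covered the widest range on the log2(CPM + 1) scale of the receptors examined. It reached 18325 CPM in the library labelled SK-GT-4 (95% interval 18278 to 18373), 3515 CPM in ESO-51 and 1387 CPM in OACP4_C, and stood at 10.4 CPM in ESO-26. OE19 is widely used as a line with an amplified ERBB2 gene, yet the library labelled OE19 held 185 CPM (179.9 to 190) and ranked 6 of 9. Each name used for a library throughout is therefore the label it carries, and no library was reassigned. ERBB2 and 10 genes beside it on chromosome 17 were scored as a list of 11, so ERBB2 itself counts in the values of this list. The list was higher in OACP4_C (1.82 on the log2 scale against the median of the other 8 libraries, 9 members over 2-fold above) and in ESO-51 (2.65, 8 members). In SK-GT-4 its median was -0.07, with 5 members over 2-fold above, among them ERBB2 itself and PPP1R1B at 8.42 CPM. PGAP3 reached 1359 CPM there, MIEN1 848 CPM and the adaptor gene GRB7 2982 CPM, while CDK12 stood at 75.1 CPM and STARD3 at 27.8 CPM. PPP1R1B was highest in OE19 (456 CPM) and ESO-51 (341 CPM).

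Other receptors peaked in different libraries. MET, the receptor of hepatocyte growth factor, reached 12506 CPM in OE19 and 6323 CPM in OACP4_C, against 57.7 CPM in OE33. EGFR was highest in OACP4_C (857 CPM) and OAC_5.1_C (762 CPM) and lowest in ESO-26 (6.11 CPM). ESO-26 instead held PDGFRA at 1233 CPM, FGFR2 at 459.8 CPM, FGFR1 at 285 CPM and IGF1R at 266 CPM. FGFR2 also reached 149 CPM in OAC_5.1_C, where AXL was 1449 CPM. ERBB3 was 726 CPM in OE19 and 511 CPM in SK-GT-4, FGFR3 was 134 CPM in ESO-51, EPHA2 was 547 CPM in OE19, and RET was 17.8 CPM in OE33. Among other genes known to be amplified in this cancer, CDK6 was highest in ESO-26 (1548 CPM), the cyclin gene CCND1 in JH_EsoAd1 (1285 CPM), CCNE1 in OAC_5.1_C (73.6 CPM) and MYC in OE19 (466 CPM). VEGFA reached 493 CPM in SK-GT-4 and 399.7 CPM in ESO-51. GATA6 was 91.5 CPM in SK-GT-4 and 0.377 CPM in OE33, whereas GATA4 was highest in OE33 at 23.2 CPM. MDM2 stayed within 4-fold of the median of the other libraries in every line.

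Tumour suppressor genes next to each other on chromosome 9 were nearly silent in the same 3 libraries. CDKN2A, which encodes the inhibitors p16 and p14ARF, had 3 counts in FLO-1, 1 count in JH_EsoAd1 and 0 counts in OAC_5.1_C (floor 0.0617 CPM). It ranged from 15.4 CPM (SK-GT-4) to 154 CPM (OE19) elsewhere. CDKN2B had 5 counts in FLO-1, 1 count in OAC_5.1_C and 0 counts in JH_EsoAd1 (floor 0.149 CPM), and the adjacent metabolic gene MTAP was 3.56 CPM, 0.103 CPM and 1 count in these libraries, against 143 CPM in OACP4_C. SMAD4, a mediator of TGF-beta signalling, was 7.47 CPM in OAC_5.1_C, its receptor gene TGFBR2 was 3.58 CPM in ESO-26, the chromatin remodeller SMARCA4 was 12.7 CPM in OE33, and WWOX was 1.21 CPM in OE19. ARID1A, APC, FHIT and RB1 lay within 4-fold of the median of the other libraries in each line, as did the mismatch repair genes MSH6 and PMS2.

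Of the genes for cytotoxic drug targets, TOP2A and RRM2 were over 4-fold lower in OE19 than the median of the other libraries. TOP2A ranged from 186 CPM in OE19 to 1370.1 CPM in OAC_5.1_C. RRM2 was likewise lowest in OE19 (30.2 CPM), while TYMS, TOP1, RRM1, TUBB3 and ERCC1 did not pass 4-fold in any library. The adhesion antigen EPCAM was 1335 CPM in ESO-51, 5.13 CPM in ESO-26 and 0.189 CPM in OE33. CEACAM6 was highest in SK-GT-4 (953 CPM) and CEACAM5 in OE19 (284 CPM). CD274, which encodes PD-L1, was 59.1 CPM in OAC_5.1_C and 45.4 CPM in OACP4_C, with at most 6.44 CPM elsewhere. The gastric tight junction gene CLDN18 was 18.97 CPM in SK-GT-4, where MUC1 reached 214 CPM and NECTIN4 63.3 CPM, and mesothelin (MSLN) was highest in OACP4_C (147 CPM).

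**Figure D1:**
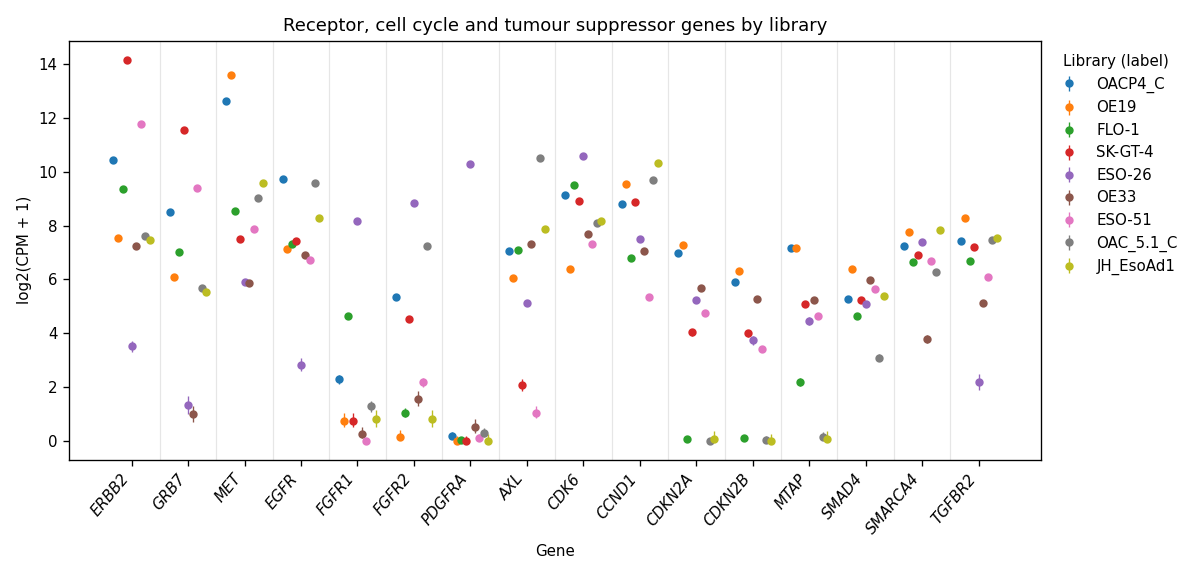
Levels of 16 receptor, cell cycle and tumour suppressor genes, given along the horizontal axis, as log2(CPM + 1) on the vertical axis, each point 1 of the 9 libraries with its Poisson 95% interval as a bar. ERBB2 is highest in the library labelled SK-GT-4 and ranks 6 of 9 in the library labelled OE19.

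ESO-26 and OE33 stood apart from the other libraries in overall expression. Across 17129 genes the 36 pairs of libraries had a median Pearson r of 0.811, and these 2 libraries (median r with the others 0.763 for ESO-26 and 0.790 for OE33) formed a cluster of their own, with r = 0.834 between them. The closest pair was OACP4_C and OAC_5.1_C (r = 0.891) and the most distant was SK-GT-4 and ESO-26 (r = 0.740). The first principal component, 24.4% of the variance, set ESO-26 and OE33 against the rest, and the second, 16.7%, ran from SK-GT-4 to OAC_5.1_C. Genes are not independent replicates, and the median Spearman rho was 0.805.

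**Figure D2:**
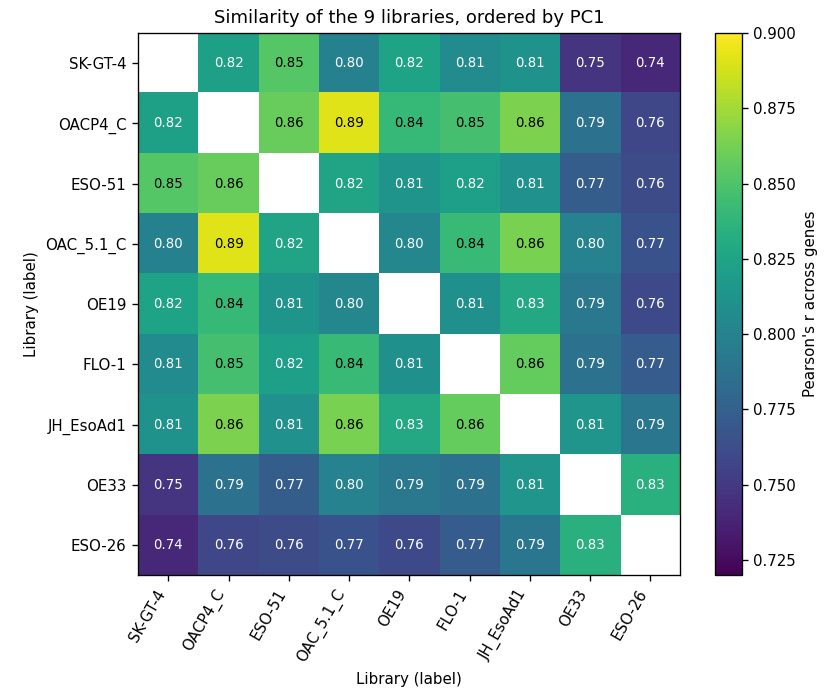
Pearson r across 17129 genes for each pair of the 9 libraries, ordered along the first principal component, with colour giving r. ESO-26 and OE33 are closer to each other (r = 0.834) than to any other library.

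Every library had genes that set it apart from the other 8 by at least 4-fold from the nearest one. Over the 9 libraries 1086 genes were higher and 406 were lower by this rule. ESO-26 had 181 higher and 175 lower genes, OE33 181 and 46, FLO-1 160 and 12, SK-GT-4 131 and 56, OAC_5.1_C 128 and 11, ESO-51 101 and 21, JH_EsoAd1 96 and 10, OE19 71 and 59, and OACP4_C 37 and 16. The counts depended on scale. A pseudocount of 5 gave 603 higher and 137 lower genes, a 2-fold gap 2774 and 1139, the deposited FPKM 450 and 35, and FPKM rescaled to equal sums 437 and 41. Without OAC_5.1_C the OACP4_C library had 62 higher genes; lower genes numbered 333 in ESO-26 without OE33, 36 in ESO-51 without SK-GT-4 and 17 in OAC_5.1_C without ESO-26, and OE33 had 170 without ESO-26 and 71 without OE19. Of the 63 genes taken by rank, 44 kept the gap in every setting. All 63 kept it without each other library in turn, which the rule fixes, since leaving out another library can only keep or widen a gap. The 19 that lost the gap with deposited or rescaled FPKM, some also with a pseudocount of 5, included UGT2B7, DDX43, CD22, LPCAT2, ZNF264, OGFRL1, EHBP1L1, DCTD, SLC38A1, ME1, ZNF160, KIAA0355, ARHGEF10, ZNF268, AL592490.1, CDH2, FOCAD and KLHL9.

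In SK-GT-4 the protein-coding genes with the largest gaps upward were LYZ, encoding lysozyme (2089.9 CPM, next library 1.98 CPM, gap 9.46 log2 units), the gastric protease gene CTSE (869 CPM, next 0.885 CPM), PHGR1 (547 CPM), the sulphotransferase gene SULT1B1 (181 CPM) and the secreted phospholipase gene PLA2G2A (139 CPM, next 2 counts). ESO-51 led in CEL, a bile salt-dependent lipase (1856 CPM, next 4.66 CPM, gap 8.36), the dipeptidase gene DPEP1 (271 CPM), the intestinal stem cell marker OLFM4 (227 CPM), TSPOAP1 (227 CPM) and TMEM176A (73.3 CPM). OE19 led in the alcohol dehydrogenase gene ADH1C (374 CPM, next 0.912 CPM, gap 7.62), the gluconeogenic enzyme gene PCK1 (398 CPM), the membrane mucin gene MUC17 (607 CPM, next 9.61 CPM), CREB3L3 (85.9 CPM) and TNFAIP6 (99.6 CPM, next 1 count). Reads of ADH1C may be shared with its near-identical neighbours ADH1A and ADH1B. The largest gaps downward were the integrin gene ITGAV (0.143 CPM, lowest other 106 CPM) and OGFRL1 (0 counts, floor 0.107 CPM) in OE19, ZNF160 (0 counts, floor 0.0667 CPM) and KIAA0355 (0.356 CPM) in ESO-51, and the amino acid transporter genes SLC38A2 (0.386 CPM, lowest other 277 CPM) and SLC38A1 (0.675 CPM, lowest other 196 CPM) in SK-GT-4.

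By the same ranking ESO-26 held SCRG1 at 2179 CPM (next 1.25 CPM, gap 9.92), PDGFRA at 1233 CPM (next 0.415 CPM), FAM9C at 844 CPM (next 3 counts), the small heat shock protein gene CRYAB at 733 CPM and the germ cell gene DPPA3 at 153 CPM (next 2 counts). S100A11 was low there, at 0.231 CPM. OE33 held TDRD12, a gene of the germline piRNA pathway, at 788 CPM (next 0.864 CPM, gap 8.72), the cancer-testis genes MAGEA4 at 328 CPM (next 3 counts) and PASD1 at 75.9 CPM (next 1 count), the chemokine gene CCL2 at 207 CPM (next 2 counts) and the neurofilament gene NEFH at 139 CPM. The malic enzyme gene ME1 had 0 counts in OE33 (floor 0.113 CPM, lowest other 56.9 CPM), and SFN, encoding 14-3-3 sigma, was 0.528 CPM.

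In OAC_5.1_C the leading genes included the keratin gene KRT81 at 943 CPM (next 4.97 CPM, gap 7.31), whose reads KRT86 may share, and the keratin-associated protein gene KRTAP2-3 at 34.8 CPM. HSD11B1, which regenerates cortisol, was 156 CPM there, C6orf15 166 CPM and NLRP10 44.7 CPM, while ARHGEF10 (0.144 CPM, lowest other 19.6 CPM) and ZNF268 (0.0823 CPM) were low. JH_EsoAd1 led in CALB1, encoding a calcium-binding protein (809 CPM, next 0.867 CPM, gap 8.76), the squamous keratin gene KRT4 (523 CPM, next 7.29 CPM), AL592490.1 (90.9 CPM) and the N-cadherin gene CDH2 (101 CPM), and had 1 count of FOCAD and 0 counts of KLHL9 (floor 0.149 CPM). FLO-1 led in the neural adhesion gene CNTN1 (677 CPM, next 1.73 CPM, gap 7.95), the protease inhibitor gene TFPI2 (239 CPM), the proteoglycan gene SRGN (176 CPM), the neuropeptide Y receptor gene NPY1R (124 CPM) and SMOC1 (92.5 CPM), with EHBP1L1 at 0.640 CPM (lowest other 47.6 CPM) and 1 count of DCTD. OACP4_C led in UGT2B7 (23.4 CPM, next 0.579 CPM, gap 3.95), DDX43 (21.7 CPM), the interleukin-33 receptor gene IL1RL1 (113 CPM, next 9.27 CPM), CD22 (41.7 CPM) and the metalloproteinase gene MMP7 (405 CPM, next 40.7 CPM). LPCAT2 had 3 counts there and ZNF264 0 counts (floor 0.0518 CPM).

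Several of the lowest genes were neighbours on a chromosome in the order of expressed protein-coding genes, so genes left out of that order may lie between them. In SK-GT-4, SLC38A1 and SLC38A2 ended a run of 8 low genes on chromosome 12, with PUS7L, IRAK4, TWF1, ANO6, ARID2 and SCAF11, of which IRAK4 had 0 counts (floor 0.0965 CPM) and ANO6 had 3. In ESO-26 a run of low genes on chromosome 22 included PPM1F, TOP3B, BCR, CHCHD10 and SMARCB1. SMARCB1, which encodes a core subunit of the SWI/SNF chromatin remodeller, had 0 counts there (floor 0.173 CPM, lowest other 20.3 CPM) and BCR had 2 counts (lowest other 51.0 CPM). In FLO-1, DCTD was followed by WWC2 and CDKN2AIP on chromosome 4, with 3 and 2 counts. FOCAD and KLHL9, low in JH_EsoAd1, are neighbours on chromosome 9 in that order. CDKN2A, CDKN2B and MTAP, nearly silent in JH_EsoAd1 too, are on the same chromosome but were left out of that order, being low in other libraries as well. The members of these runs beyond the genes named by rank were chosen after their values were seen.

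**Figure D3:**
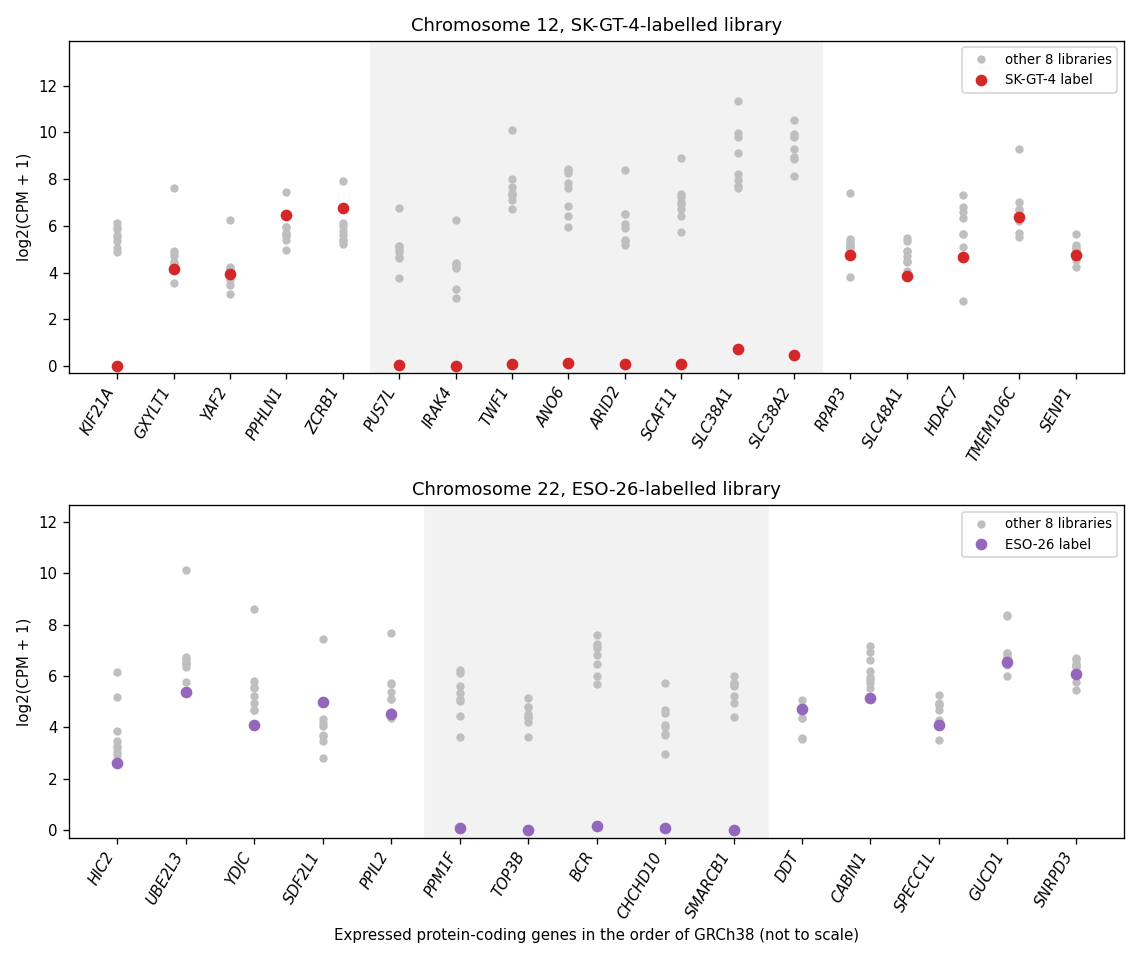
Levels as log2(CPM + 1) of genes in chromosomal order, on chromosome 12 around the low run in the library labelled SK-GT-4 and on chromosome 22 around the low run in the library labelled ESO-26, with the other 8 libraries in grey and the run shaded. The 8 genes of the first run had 0 to 21 counts and the genes shown of the second 0 to 2 counts.

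Gene lists fixed in advance were used to ask which programmes set a library apart. Each list's median difference from the other 8 libraries was ranked among 10000 random lists of matched expression, and 102 of 261 pairs of list and library lay at or beyond percentile 1 or 99, 62 of them higher and 40 lower. Chance gives 2% for unrelated genes, against 39.1% here, and since members of a list vary together this is a description of these libraries, not a test. Of the 102 calls, 64 held in every setting and without each other library in turn.

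Columnar transcription factors, which specify gut epithelium, were higher in ESO-51 (2.06 on the log2 scale, 8 of 14 members over 2-fold above the other libraries), SK-GT-4 (1.75, 9 members) and OE19 (1.06, 8 members). HNF4A was 167 CPM, 138 CPM and 124 CPM in these libraries, and CDX2 was 99.9 CPM in ESO-51, 78.4 CPM in OE19 and 6.85 CPM in SK-GT-4. The list was lower in OE33 (-1.16, 8 members below) and ESO-26 (-1.04, 7 members). ELF3 was 0.792 CPM in OE33 and 0.346 CPM in ESO-26, against a median of 178 CPM over the libraries other than ESO-26. Intestinal differentiation was higher in OE19 (2.15, 11 of 15 members) and ESO-51 (1.92, 12 members), led by the lectin gene LGALS4 (1655 CPM) and cadherin gene CDH17 (680.5 CPM) in OE19 and by CDH17 (786 CPM), villin (VIL1, 283 CPM) and GUCY2C (132 CPM) in ESO-51. In SK-GT-4 the median over members was 0.19 and not called, but 6 members were over 2-fold above and the mean was 2.89, against 2.91 in OE19 and 3.40 in ESO-51. Gastric differentiation was called in SK-GT-4 (4.75, 12 of 15 members), with CTSE, TFF1 (341 CPM), ANXA10 (334 CPM) and MUC5AC (278 CPM), and not in FLO-1 (0.65, percentile 97.6, 7 members above) or OE19 (5 members above, mean over members 1.91). Mucins were higher in SK-GT-4 (2.59), FLO-1 (2.23) and OE19 (1.94, with MUC5B at 1901 CPM and MUC5AC at 1542 CPM) and lower in OE33 (-1.61, 7 of 12 members). Squamous and basal genes were higher in JH_EsoAd1 (2.17, 11 of 16 members), FLO-1 (1.39) and OAC_5.1_C (1.12) and lower in OE33 (-0.46), and the basal regulator TP63 was 292 CPM in JH_EsoAd1, where KRT13 was 177 CPM. Posterior HOX genes were higher in OE19 (1.31, HOXA13 60.4 CPM) and OE33 (1.14, HOXB9 42.7 CPM) and lower in JH_EsoAd1 (-1.30, 6 of 10 members). With FPKM the calls for mucins in FLO-1, OE19 and OE33, squamous genes in OE33, columnar factors in OE19 and HOX genes in JH_EsoAd1 ended, and others ended with a pseudocount of 5 (columnar factors in OE19 and ESO-26, squamous genes in OE33) or with the mean over members or no member filter (HOX genes in OE33). The mucin value in OE33 shrank to -0.72 without OE19 or SK-GT-4, -0.88 without FLO-1, -0.97 without ESO-51 and -1.0 without JH_EsoAd1.

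Epithelial junction genes were called in 8 of the 9 libraries. The list was lower in ESO-26 (-5.29, 19 of 20 members) and OE33 (-4.02, 16 members), and also in OE19 (-1.52, 11 members) and JH_EsoAd1 (-1.30, 11 members). E-cadherin (CDH1) had 3 counts in ESO-26 against a median of 302 CPM elsewhere, the claudin gene CLDN4 was 1.79 CPM there, and KRT19 was 15.99 CPM in OE33. In OE19 the epithelial splicing regulator ESRP1 had 3 counts and the epithelial transcription factor gene GRHL2 had 2. OAC_5.1_C (1.85, 16 members above), OACP4_C (1.24) and SK-GT-4 (1.04) were higher, with KRT19 at 9611 CPM in OACP4_C. Mesenchymal genes were higher in JH_EsoAd1 (1.46, 13 of 21 members), where fibronectin (FN1) was 521 CPM and TGFBI 433 CPM. Matrix proteases and plasminogen genes were higher in OAC_5.1_C (1.63, PLAU 356 CPM), OE19 (0.98, MMP1 2521 CPM) and JH_EsoAd1 (0.97) and lower in ESO-26 (-0.86, PLAU 0.288 CPM). Targets of the coactivator YAP were higher in OAC_5.1_C (1.42, 13 of 18 members), with ANKRD1 at 323 CPM, CCN1 at 499 CPM and TGFB2 at 439.6 CPM, and in OACP4_C (1.02) and OE33 (0.61), and lower in ESO-51 (-0.93) and SK-GT-4 (-0.85). The epithelial value was 1.16 in OAC_5.1_C without ESO-26 or OE33 and 1.21 without JH_EsoAd1, and 0.72 in OACP4_C without OE19, OE33 or JH_EsoAd1 and 0.78 without ESO-26; the YAP value was 0.55 in OACP4_C without ESO-26 or ESO-51, 0.98 in OE33 without OACP4_C or OAC_5.1_C and -0.52 in ESO-51 without OAC_5.1_C. The protease calls in OE19 and ESO-26 ended with a pseudocount of 5 or FPKM, that in JH_EsoAd1 with a pseudocount of 5, and the YAP call in OE33 with the mean over members.

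OE19 stood apart by low expression of cell cycle genes. Mitosis genes were lower there (-1.45, 16 of 20 members), as were DNA replication genes (-1.57, 14 of 16), with BIRC5 at 6.24 CPM, CDK1 at 37.8 CPM, E2F1 at 6.81 CPM and PCNA at 34.5 CPM. Mitosis genes were higher in ESO-26 (0.84, KIF20A 264 CPM) and OAC_5.1_C (0.74, CCNB2 199.9 CPM), and replication genes in FLO-1 (0.58, MCM7 826 CPM) and JH_EsoAd1 (0.53, MCM4 473 CPM).

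Interferon response genes and MHC class I genes moved widely between libraries. The interferon list was higher in OACP4_C (2.03, 16 of 19 members), ESO-51 (1.58, with IFI27 at 665 CPM and MX1 at 444 CPM), OE33 (1.48) and FLO-1 (0.71) and lower in ESO-26 (-3.44, 18 members), SK-GT-4 (-2.59, 15 members) and JH_EsoAd1 (-0.70). IFIT1, IFIT2 and IFIT3 had 3, 2 and 1 counts in SK-GT-4, against medians of 42.2, 51.6 and 45.3 CPM elsewhere. MHC class I presentation was higher in OACP4_C (1.91, 11 of 12 members), OE33 (1.03) and OAC_5.1_C (0.89, HLA-B 1371 CPM) and lower in SK-GT-4 (-2.60, 11 members, HLA-B 18.2 CPM), ESO-26 (-1.43, PSMB8 0.577 CPM) and JH_EsoAd1 (-1.31, HLA-C 78.4 CPM). MHC class II genes were low everywhere, with a higher list in OE33 (0.99), where HLA-DPA1 was 5.66 CPM. NF-kB cytokines were higher in OACP4_C (1.63, LIF 170.4 CPM), FLO-1 (1.30, BIRC3 146 CPM) and OE19 (1.29, IL1B 139 CPM) and lower in ESO-26 (-2.04, 11 of 14 members) and OE33 (-0.71). Haematopoietic and endothelial lists, markers of other cell types, were called in 0 libraries, though the haematopoietic list came close in OAC_5.1_C (0.83, percentile 98.90) and JH_EsoAd1 (0.81, percentile 98.86) and the endothelial list was at percentile 97.55 in OAC_5.1_C (0.67) and 96.98 in JH_EsoAd1 (0.65). With FPKM or the mean over members the calls for MHC class I in OAC_5.1_C, MHC class II in OE33 and NF-kB in OE33 ended, as did those for NF-kB in FLO-1 with the mean and interferon in JH_EsoAd1 with FPKM, and HLA reads can be shared between these genes. The interferon value in OE33 was 0.87 without ESO-26 or JH_EsoAd1.

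Detoxifying enzymes under NRF2 control, a regulator of the oxidative stress response, were called in 5 libraries. The list was higher in SK-GT-4 (1.30, 8 of 14 members) and ESO-26 (1.09, 8 members), with AKR1B10 at 1521 CPM in the former and AKR1C1 at 6288 CPM and NQO1 at 3158 CPM in the latter, and lower in OE33 (-1.69, 9 members), OACP4_C (-1.34) and OAC_5.1_C (-0.79). The AKR1C genes are near-identical and may share reads. Cholesterol synthesis was higher in OAC_5.1_C (1.01, HMGCS1 665 CPM) and ESO-26 (1.01, LSS 234 CPM) and lower in ESO-51 (-1.30, 10 of 14 members). Drug transport and metabolism was higher in OE19 (1.85, 12 of 17 members), with ALDH1A1 at 881 CPM and DPYD, which degrades fluorouracil, at 101 CPM, and lower in ESO-26 (-2.10) and OE33 (-1.43, ABCG2 0.415 CPM). Hypoxia and glycolysis genes were lower in OE33 (-1.10, SLC2A1 26.6 CPM). The unfolded protein response was higher in ESO-51 (0.82, DDIT3 51.4 CPM) and lower in FLO-1 (-0.89, DDIT3 3.61 CPM). The hypoxia call ended with the mean over members. Without SK-GT-4 the NRF2 value was -1.09 in OE33 and -0.87 in OACP4_C, which also had -0.87 without OE19, and the drug list in ESO-26 was -1.36 without OACP4_C, OE19, FLO-1 or OE33 and -1.40 without SK-GT-4 or ESO-51.

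Wnt target genes were higher in SK-GT-4 (3.02, 8 of 11 members) and ESO-51 (2.72, 9 members). The feedback inhibitors AXIN2, NOTUM and RNF43 were 111, 87.4 and 134 CPM in SK-GT-4, and RNF43 was 162 CPM and the stem cell factor ASCL2 70.9 CPM in ESO-51. The list was lower in FLO-1 (-0.54, RNF43 1.84 CPM), a call that ended with a pseudocount of 5 or FPKM. Cancer-testis antigens, normally silent outside the germline, were higher in OE33 (5.05, 6 of 9 members, PRAME 326 CPM) and SK-GT-4 (4.66, 5 members, MAGEA3 124 CPM and CTAG2 92.6 CPM), the latter ending without a filter on members; reads of MAGEA3 and MAGEA6 can be shared. Neuroendocrine genes were higher in OE33 (2.29, 5 of 8 members), with UCHL1 at 212 CPM, NCAM1 at 85.7 CPM and SYP at 16.8 CPM.

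A further 17 calls ended without 1 of the other libraries. The mesenchymal list in ESO-26, where FN1 was 3591 CPM, COL3A1 311 CPM and POSTN 108 CPM, had a value of 1.0 that was 0.08 without OE19 or ESO-51, 0.13 without SK-GT-4 or OE33 and 2.14 without FLO-1 or JH_EsoAd1. In ESO-51 the mesenchymal value of -0.75 became -0.36 without OAC_5.1_C or JH_EsoAd1, the call ending for OAC_5.1_C, and -0.50 without ESO-26. The epithelial value there, 0.96, ended at 0.41 without ESO-26 or OE33 and 0.44 without JH_EsoAd1 and was 1.52 without OACP4_C, FLO-1, SK-GT-4 or OAC_5.1_C, and its NF-kB value, -0.75, ended at -0.26 without OACP4_C and -0.41 without FLO-1. Columnar factors in JH_EsoAd1 (-0.47) turned to 0.11 without OE19 or ESO-51 and 0.04 without SK-GT-4, ended at -0.37 without OACP4_C, and were -0.75 without ESO-26 and -0.87 without FLO-1, OE33 or OAC_5.1_C; YAP targets there (0.52) ended at 0.39 without ESO-51. In OE19, YAP targets (-0.48) ended at -0.27 without OACP4_C, -0.22 without FLO-1, -0.42 without ESO-26, -0.16 without OAC_5.1_C and -0.04 without JH_EsoAd1, and turned to 0.044 with FPKM. Hypoxia genes in OE19 (0.68) ended at 0.63 without OACP4_C, SK-GT-4 or ESO-26 and 0.65 without OE33 or JH_EsoAd1, and bile acid handling (0.57, FABP6 12.8 CPM), the single call of that list, at 0.44 without FLO-1. In OAC_5.1_C the 17q12 list (-0.80) ended at -0.03 without OACP4_C or FLO-1, -0.38 without SK-GT-4 and -0.37 without ESO-51, the interferon list (-0.58) at -0.35 without OACP4_C, FLO-1 or ESO-51, with -0.91 without SK-GT-4, ESO-26 or JH_EsoAd1, and NF-kB cytokines (1.03, BIRC3 1814 CPM) at 0.57 without SK-GT-4, ESO-26 or ESO-51. In FLO-1 the 17q12 list (1.0) ended at 0.65 without ESO-26 or OAC_5.1_C, and in ESO-26 Wnt targets (-0.82) ended at -0.68 without SK-GT-4, ESO-51 or OAC_5.1_C. In OACP4_C the protease list (0.59, MMP7 405 CPM) ended at 0.34 without ESO-26 or ESO-51, 0.38 without OE33 and 0.45 without JH_EsoAd1, and cholesterol synthesis (-0.48) at -0.35 without ESO-26 or OAC_5.1_C, and the protease list in OE33 (-0.55) ended at -0.48 without OE19 and -0.52 without ESO-26.

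**Figure D4:**
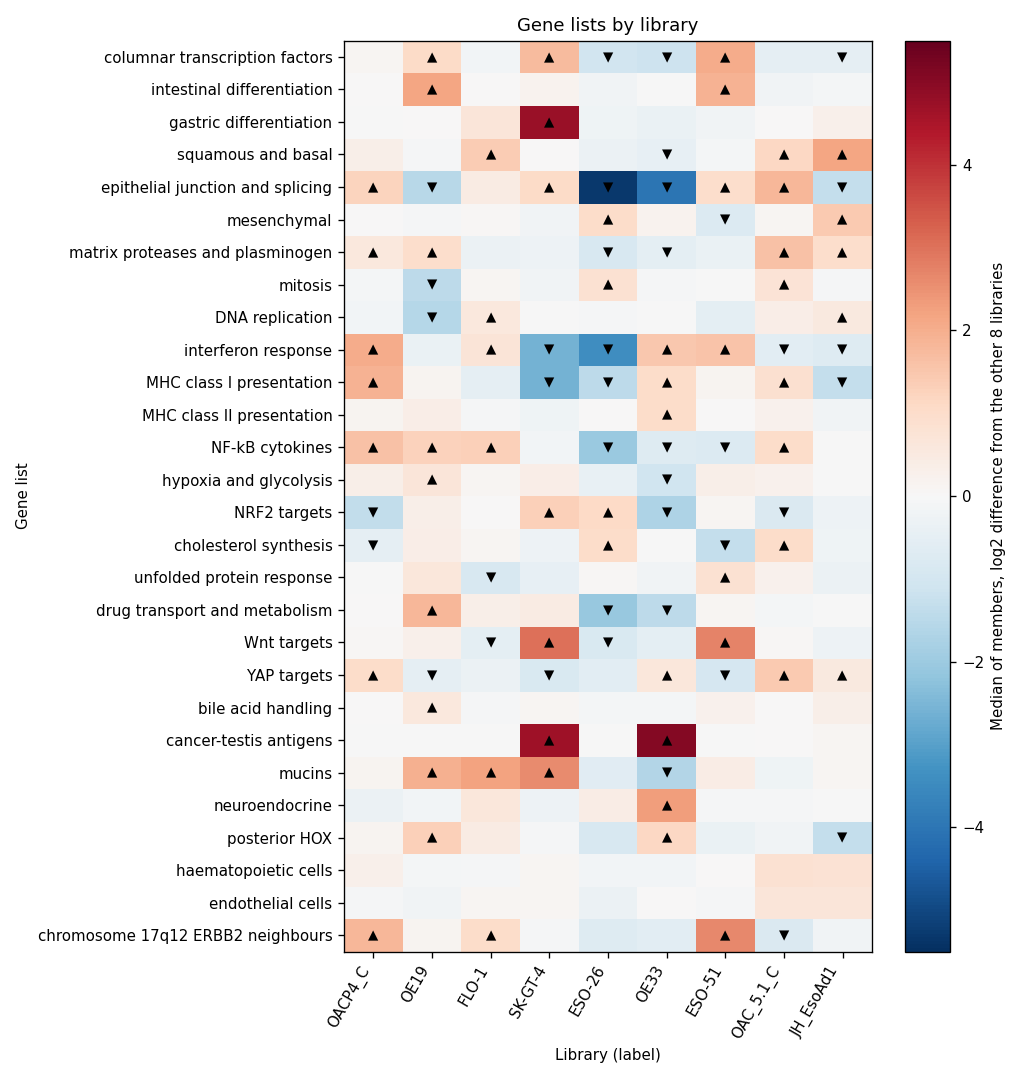
Median log2 difference from the other 8 libraries for gene lists in the 9 libraries, with colour giving the difference and triangles marking higher and lower calls. The gastric list is called in SK-GT-4, and the epithelial list is lowest in ESO-26.

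Of the 14 relations fixed in advance, 5 passed an adjusted p of 0.05 over the 9 libraries, and CDX2 and HNF4A were handled apart. Libraries with more ZEB1, a repressor of epithelial genes, had less of the epithelial list (Pearson r = -0.90, exact two-sided permutation p = 0.00139, adjusted p = 0.00733). Its Spearman rho was -0.72 (exact permutation p = 0.0369, adjusted p = 0.0860), and r was -0.83 without ESO-26 and OE33 (exact permutation p = 0.025). ERBB2 rose with its neighbour GRB7 (r = 0.91, exact permutation p = 0.000810, adjusted p = 0.00733, rho = 0.97, exact permutation p = 0.000165, adjusted p = 0.00231), and r was 0.81 without SK-GT-4 and ESO-51 (exact permutation p = 0.0125). NLRC5, the transactivator of MHC class I genes, rose with the rest of that list (r = 0.89, exact permutation p = 0.00157, adjusted p = 0.00733, rho = 0.87, exact permutation p = 0.00451, adjusted p = 0.0316), with r = 0.91 without OACP4_C and ESO-26 (exact permutation p = 0.00675). The interferon list rose with the MHC class I list (r = 0.82, exact permutation p = 0.00724, adjusted p = 0.0156, rho = 0.78, exact permutation p = 0.0172, adjusted p = 0.0603), with r = 0.88 without ESO-26 and ESO-51 (exact permutation p = 0.0107). Without OACP4_C this adjusted p was 0.0525. TP63 rose with the other squamous genes (r = 0.78, exact permutation p = 0.00248, adjusted p = 0.00868, rho = 0.68, exact permutation p = 0.0537, adjusted p = 0.107), but the relation rests on FLO-1 and JH_EsoAd1, without which r was 0.60 (exact permutation p = 0.174); it ended with FPKM (r = 0.42) and without JH_EsoAd1 alone (r = 0.66).

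The other relations did not pass. Adjusted values from exact permutation tests were 0.0510 for DNA replication against mitosis genes (r = 0.76, rho = 0.52), 0.104 for mesenchymal against epithelial genes (r = -0.64, rho = -0.47), 0.147 for MYC against DNA replication (r = -0.58, rho = -0.18) and 0.166 for GATA6 against gastric genes (r = 0.55, rho = 0.43). They were 0.340 for CIITA against MHC class II genes (r = 0.40, rho = 0.43), 0.393 for YAP targets against mesenchymal genes (r = 0.34, rho = 0.32) and 0.883 for squamous against columnar genes (r = -0.06, rho = -0.03). Without the 2 libraries farthest from the median of the first measure, r was 0.42 for replication against mitosis genes (exact permutation p = 0.347), -0.48 for mesenchymal against epithelial genes (p = 0.254), -0.29 for MYC (p = 0.511), -0.12 for GATA6 (p = 0.788), 0.72 for CIITA (p = 0.0754), 0.78 for YAP targets (p = 0.0375) and -0.38 for squamous against columnar genes (p = 0.375), so the sign turned for GATA6. CIITA against MHC class II genes passed without OAC_5.1_C (r = 0.81, adjusted p = 0.0255, exact permutation), while r was 0.10 without OE33. CDX2 and HNF4A were not given a pooled r against intestinal genes, because OE19, SK-GT-4 and ESO-51 formed a cluster apart from the other 6 libraries in that list. Within those 6, r was 0.53 for CDX2 (rho = 0.60, exact permutation p = 0.286 and 0.242) and -0.08 for HNF4A (rho = 0.03, exact permutation p = 0.854 and 1). The replication and mitosis relation passed with DESeq2 scaling (adjusted p = 0.0494, exact permutation) or FPKM (0.0182) and without ESO-26 (r = 0.86), and r was 0.26 without OE19. MYC against replication genes turned to r = 0.14 without OE19 and 0.011 with FPKM, and squamous against columnar genes to r = 0.02 without OE19, 0.11 without ESO-51 and 0.05 without JH_EsoAd1.

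**Figure D5:**
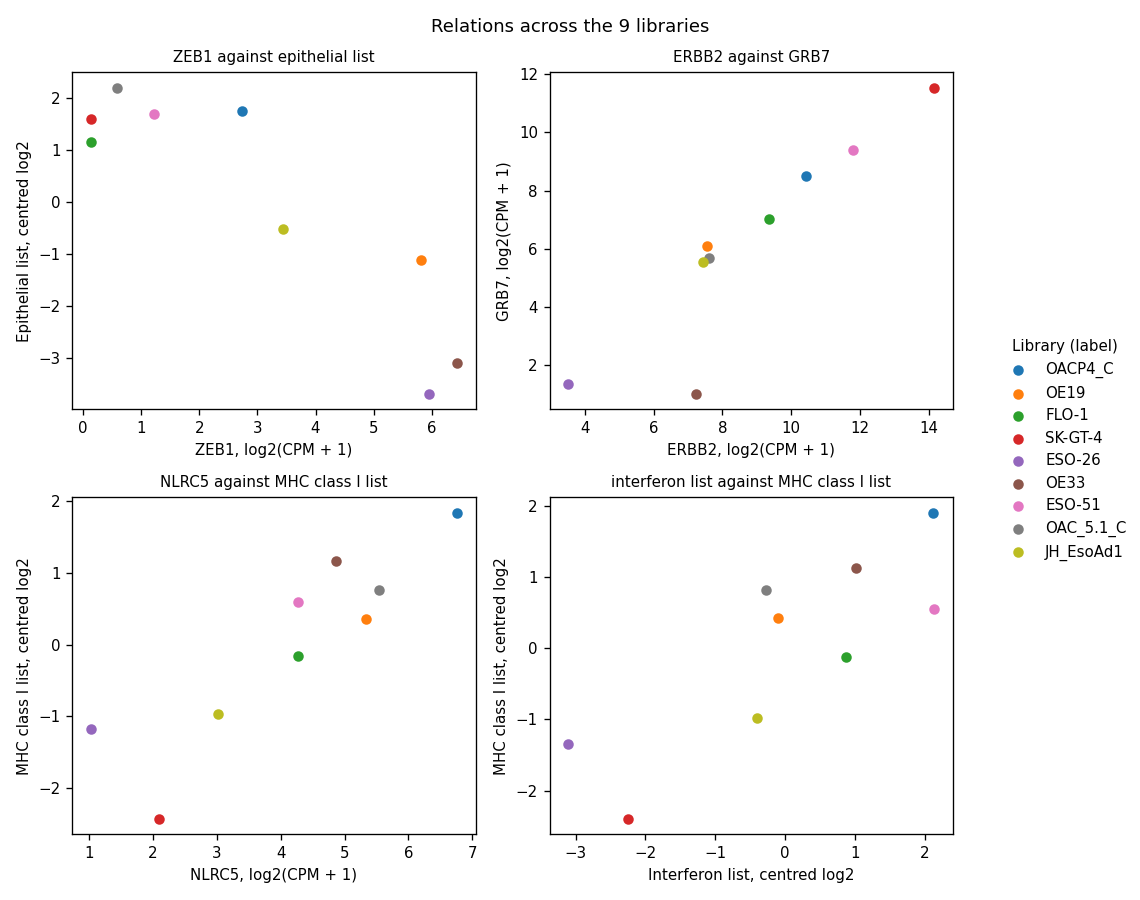
Values of the 9 libraries for 4 of the relations, each point 1 library, with log2(CPM + 1) of a gene or the mean centred log2 value of a list on each axis. ZEB1 falls as the epithelial list rises (r = -0.90), and ERBB2 rises with GRB7 (r = 0.91).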

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

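The test of an explanation in this part was chosen only after the result was seen.

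Each of 36 library measures and list values was compared across the 9 libraries for a value far from the rest, which chance gives in about 1 of 20 such groups; 6 were found. Of the counts in the table, mitochondrial genes took 24.7% in JH_EsoAd1 against 7.04% in the next library, OE33. The 10 most counted genes took 31.3% of them in JH_EsoAd1 against 15.03%. Counts of identifiers outside the table, which the comparisons do not use, made up 77.3% of the JH_EsoAd1 file against 51.0% in FLO-1. In every library 2 identifiers that the sources used here do not name held a large part of these, with a lowest share of 17.1% in ESO-26. The mean centred value of gastric genes was 3.69 in SK-GT-4, with OE19 next at 1.02. Mitosis genes stood at -1.36 in OE19, with OE33 next at -0.24, and DNA replication genes at -1.47 in OE19, with ESO-51 next at -0.41.

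The mitochondrial ribosomal share was taken of counts in the table, and that of the 2 unnamed identifiers of all counts in a line's file. JH_EsoAd1 was highest in both, at 74.8% for the identifiers against at most 47.6% (FLO-1) elsewhere. Abundant RNA carried into libraries to different extents by their preparation may account for it: over the other 8 libraries the mitochondrial ribosomal share rose with the share of these identifiers (Spearman rho = 0.88, exact permutation p = 0.00724, Pearson r = 0.87, exact permutation p = 0.00375), and r was 0.99 without OE33 and ESO-51 (exact permutation p = 0.00972). More mitochondrial RNA in the cells of that line was not tested and stays open, and no biological explanation was tested.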

How the results depend on the processing

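Leaving out each library in turn for the gene counts and the lists, and the rescaled FPKM, were alternatives chosen after seeing the data; the others were fixed before. No paired analysis was possible because each line has 1 library. DESeq2 size factors, library size alone and no CPM minimum left every count of higher or lower genes within 1.5 times. A larger pseudocount, a smaller gap and both forms of FPKM moved them, given in the order OACP4_C, OE19, FLO-1, SK-GT-4, ESO-26, OE33, ESO-51, OAC_5.1_C and JH_EsoAd1. A pseudocount of 5, which shrinks log2 differences by construction, gave 603 higher genes (18, 44, 89, 73, 109, 84, 63, 70 and 53) and 137 lower genes (2, 16, 5, 25, 63, 17, 3, 1 and 5). A 2-fold gap, a looser rule, gave 2774 higher (161, 255, 359, 355, 402, 412, 253, 347 and 230) and 1139 lower (33, 215, 39, 147, 393, 114, 120, 50 and 28). The deposited FPKM gave 450 higher (28, 43, 52, 59, 114, 48, 46, 58 and 2) and 35 lower (0, 2, 1, 3, 12, 4, 3, 0 and 10). FPKM rescaled to equal sums gave 437 higher (17, 30, 75, 52, 86, 55, 47, 59 and 16) and 41 lower (0, 3, 0, 6, 22, 5, 3, 0 and 2), so the shared divisor of the deposited FPKM, which includes counts outside the table, accounts for part of the change in higher genes of JH_EsoAd1, and the cause of the rest was not tested. Leaving out each library in turn gave 40 to 62 higher genes in OACP4_C, and lower genes numbered 178 to 333 in ESO-26, 48 to 170 in OE33, 21 to 36 in ESO-51, 11 to 17 in OAC_5.1_C and 413 to 562 in all; the gene count rises by construction where the nearest library is left out.

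The median r between libraries was 0.920 without a filter on low counts, since genes near 0 everywhere then enter, and otherwise stayed within its spread. List calls numbered 87 to 115 over the settings, and 69 of the 102 held in all 7 settings on 9 libraries and 85 without each other library in turn. YAP targets in OE19 turned to 0.044 with FPKM, and columnar factors in JH_EsoAd1 ranged from -0.87 to 0.11 with each library left out. The relations of ZEB1 with epithelial genes, ERBB2 with GRB7, NLRC5 with MHC class I genes, GATA6 with gastric genes and mesenchymal genes with epithelial genes and YAP targets changed neither call nor sign in any setting on 9 libraries or with 1 library left out. Without the 2 farthest libraries of each, r turned to -0.12 for GATA6 (exact permutation p = 0.788) and was 0.78 for YAP targets against mesenchymal genes (exact permutation p = 0.0375). Replication against mitosis genes passed with DESeq2 size factors (r = 0.76) and FPKM (0.86), and ranged from 0.26 to 0.86 with each library left out. TP63 against squamous genes no longer passed with FPKM (0.42) and ranged from 0.66 to 0.84, interferon against MHC class I genes from 0.77 to 0.86, and CIITA against MHC class II genes from 0.10 to 0.81, passing without OAC_5.1_C. MYC against replication genes turned to 0.011 with FPKM and ranged from -0.79 to 0.14, and squamous against columnar genes from -0.42 to 0.11. The causes of these changes in lists and relations were not tested. Depth sets the floor of 3 counts, from 0.0400 CPM in FLO-1 to 0.173 CPM in ESO-26, so low genes are less well resolved in ESO-26.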

Other observations

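The tests of the low runs and of the OE19 label were chosen only after the result was seen, whereas those of the high runs were written before.

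Genes high in a single library also lay side by side in the order of expressed protein-coding genes. In OAC_5.1_C, 5 neighbours on chromosome 11 were high together, with YAP1, the coactivator whose targets were high there, at 1429.8 CPM (highest other library 218 CPM), the apoptosis inhibitors BIRC3 at 1814 CPM and BIRC2 at 763 CPM, TMEM123 at 4873 CPM and CFAP300 at 58.0 CPM. On chromosome 22 the ubiquitin-conjugating enzyme gene UBE2L3 (1121 CPM, highest other 107 CPM), YDJC (391 CPM) and SDF2L1 (171 CPM) were high in the same library, and on chromosome 17 the hair keratin genes KRT33B (12.7 CPM), KRT34 (32.0 CPM) and KRT36 (13.8 CPM). In ESO-26 the run around SCRG1 on chromosome 4 held the chromatin protein gene HMGB2 (933 CPM, highest other 197 CPM), SAP30 (268 CPM), FBXO8 (360.2 CPM) and CEP44 (209 CPM). The transporter gene ABCA5 (553 CPM, highest other 19.9 CPM) was high there with ABCA6 and ABCA10. OE19 held the alcohol dehydrogenase genes ADH6 (42.9 CPM), ADH1B (42.3 CPM), ADH1A (5.67 CPM) and ADH1C in 1 run. JH_EsoAd1 held FDXR (137 CPM, highest other 31.0 CPM) with USH1G, OTOP2 and OTOP3. In OE33 the neutrophil genes ELANE (5.85 CPM) and AZU1 (5.36 CPM), both just above the minimum CPM of 5, lay beside PLPPR3 (72.8 CPM). These genes were chosen after their values were seen.

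Pooled over the 9 libraries there were 30 neighbouring pairs among 386 low genes, against a mean of 4.75 and at most 16 in 10000 draws. Among 928 high genes there were 87, against a mean of 11 and at most 23, so chance placement is excluded for that pooled count. The low count also lay above every draw, but its test was chosen after the low runs were seen and counts those same runs. ESO-26 gave 13 of the low pairs, as many as the highest of its own draws, SK-GT-4 gave 8 against at most 4, FLO-1 gave 2 against at most 1, OACP4_C and ESO-51 gave 0, and OE19, OE33, OAC_5.1_C and JH_EsoAd1 did not pass the highest of their own draws; the high pairs passed the highest of the library's own draws in OE19, SK-GT-4, ESO-26, OE33, OAC_5.1_C and JH_EsoAd1, not in OACP4_C, FLO-1 or ESO-51. Reads shared between adjacent members of a gene family are excluded as the whole cause, since 26.7% of the low pairs and 37.9% of the high pairs joined genes of similar name. Loss or gain of DNA, shared silencing and shared activation remain possible explanations and may act in different runs. DNA was not measured here, and no biological explanation was tested.

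The level of ERBB2 in the library labelled OE19, rank 6 of 9, was set against what is known of that line from outside these data. An exchange of columns when the count table was assembled is excluded, since 49075 of 50418 identifiers had equal counts in the column and file of each label. The match of 9 of 9 columns was counted over these identifiers only, so it adds nothing to this. A miscount of ERBB2 alone is left open, since of the 10 other members of the neighbour list 2 were over 4-fold above the median of the other libraries there, PPP1R1B (456 CPM) and IKZF3 (11.2 CPM), and PGAP3, MIEN1 and GRB7 were not. A library or culture that carried another line's label before counting and a subline that does not carry the amplification were not tested, and nothing here shows which line the library came from.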
